A study of Mus musculus with 6 samples.

How the data were processed

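The series holds 6 arrays, 2 for each of 3 cell fractions sorted from the sublingual mucosa of BALB/c mice, an inbred laboratory strain. The mucosa had been painted 2 times with FITC, a fluorescent contact sensitiser. Per the labels' protocols, tissue from the dorsal tongue was digested for 30 min with collagenase and DNase and the cells were sorted. Fr1 was the CD11c-positive, CD206-negative fraction, Fr2 the CD11c-negative, F480-positive, CD206-negative fraction, and Fr3 the F480-positive fraction with high CD206, where F480 stands for the macrophage antigen ADGRE1. The series design states that the 2 replicates of a fraction came from independent experiments; how many mice went into each sort is not given in the sources used here. RNA was amplified with a whole-transcriptome kit for small inputs and the cDNA was labelled with Cy3, per the labels' protocols.

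Each array had 62976 spots of an Agilent mouse design with 60-base probes, scanned in 1 channel. The spot intensity values were made by the authors with Agilent Feature Extraction 11.5.1.1, per the file headers, which subtracted the background, removed spatial and multiplicative trends and set surrogate values for dim spots. Of the spots, 59305 were not controls and held 56605 different probes. Coordinates are those of the files, on the mouse build mm9; no genome was used here, and the place of a probe in an exon or UTR is not given. The authors' deposited value table holds log2 values whose column medians lay between −2.44 and −2.25 and whose 75th percentile was 0 on every array. Set against the scanner values it correlated with r of at least 0.9999 (Pearson, across probes), so its scale, centring and direction were settled, and it served as an alternative. On the Fr2 arrays 91.7% and 90.7% of its probes lay within 0.05 of the array's median difference, against 100% on the other arrays.

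Spots of one probe were averaged. Signals were taken as log2 of the processed intensity minus each array's 75th percentile, and levels below are on this scale. A probe was kept when it was well above background on both arrays of at least 1 fraction, which left 27867 probes; 4 probes were left out for an outlier flag on a single spot. A gene was represented by its brightest kept probe, which gave 20817 genes, of which 5123 had over 1 probe kept. Gene names were updated through a RefSeq table: 32994 probes matched by accession, 10224 by symbol and 520 by synonym, and 12867 kept the name in the files. Of the genes tested, 7893 matched a name filter for clone, accession, Gm, LOC, RIKEN, microRNA and lincRNA probe names. The filter also took in names that open with a digit, or with a letter and a digit, such as S100a8 and F13a1.

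Groups were compared with limma 3.58.1 in R 4.3.3, in a model of 3 group means over all 6 arrays with moderated variances and Benjamini-Hochberg adjustment; files were read with Python 3.11.15. A call is an adjusted p under 0.05. All p-values are two-sided, and adjusted p-values of genes come from limma. The 3 pairwise comparisons used moderated t-tests, and a separate moderated F-test covered the 3 fractions. Gene lists were tested with camera at a preset inter-gene correlation of 0.01, adjusted over the 30 lists of a comparison, with camera at an estimated correlation and fry as alternatives. Camera compares a list with the other genes, and fry tests whether its genes move on balance one way. Member counts adjusted over the list alone are given beside those over all genes. Where no probe of a gene was well above background on either array of a fraction, the difference is given as "at least N-fold": the brighter fraction's mean against the dimmer fraction's mean of, per array, the higher of the probe's own signal and the lowest signal well above background.

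The lists, fixed from general knowledge, were pan conventional dendritic cell (DC), cDC1, cDC2, Langerhans cell, mature migratory DC, costimulatory and coinhibitory ligands, MHC class II presentation, macrophage core, resident CD206-high macrophage, complement and apoptotic cell uptake, scavenger, lectin and Fc receptors, lysosome, monocyte, inflammatory cytokines and chemokines, alternative activation, tolerance associated, interferon response, cell cycle, matrix remodelling and angiogenic factors, and dissociation stress. Lists of other cell types covered neutrophil, eosinophil, mast cell and basophil, T and NK cell, B and plasma cell, plasmacytoid DC, epithelium, fibroblast, endothelium and skeletal muscle. The rule for named genes took the 3 sort markers and from each list up to 4 members with the smallest p. It also took the 10 called genes with the largest difference in each direction that did not match the name filter (none qualified). It gave 349 pairs of gene and comparison over 219 genes. In 26 pairs, over 21 genes, another kept probe of the gene had the opposite sign. The lists, this rule, the groups, the tests and most alternatives were fixed before the data were examined.

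The alternatives were another background correction (normexp, offset 50), quantile scaling, scaling to the median of probes above background on all arrays, no filter, a stricter filter, the mean of all probes of a gene, the replicate number as a block, a trended and robust variance, array weights, only the arrays compared, a 2-fold minimum, a stricter adjusted p of 0.01, the deposited table, and each array left out in turn. Scaling to the 75th percentile of probes above background on all arrays, taking off a curve of signal on probe T content, and leaving out probes with over 30% T were added after the data had been seen. Slide as a block was not run, because the slide that held Fr2 held no other fraction.

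The test was checked on simulated values for the same 20817 genes, with 50 genes changed at each of 4 sizes. At log2 1 and 2 no changed gene was recovered in any comparison. At log2 4, limma recovered 3 of 50 for Fr1 against Fr2 and 0 of 50 for each of the other comparisons. At log2 6 it recovered 27 of 50 for Fr1 against Fr2, 28 for Fr1 against Fr3 and 27 for Fr2 against Fr3. False calls numbered 1, 3 and 0. The number of arrays limits the precision of all values.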

Results

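Gene expression was measured on 1-colour arrays in 3 fractions of mononuclear phagocytes from mouse sublingual mucosa, to compare the profiles of dendritic cell and macrophage subsets: CD11c-positive CD206-negative cells (Fr1), CD11c-negative F480-positive CD206-negative cells (Fr2) and F480-positive CD206-high cells (Fr3), with 2 arrays each. Spots well above background made up 46.6% and 44.6% on the Fr1 arrays, 51.9% and 52.4% on the Fr2 arrays and 52.0% and 46.5% on the Fr3 arrays, and no spot was saturated (0 on every array). The Fr1 and Fr3 arrays shared 1 slide and scan and both Fr2 arrays lay on the other slide, so differences between Fr2 and another fraction cannot be told apart from the slide. Across the 20817 genes tested, replicate arrays correlated with r = 0.883 in Fr1, 0.898 in Fr2 and 0.796 in Fr3 (Pearson, across genes, which are not independent replicates). The 2 Fr3 arrays stood apart from each other: 1602 genes were over 8-fold lower on replicate 2 and 241 over 8-fold higher, against 298 and 213 in Fr1 and 361 and 142 in Fr2. The genes lower on that array were mostly ones with T-rich probes, as the plot by probe T content shows.

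**Figure D1:**
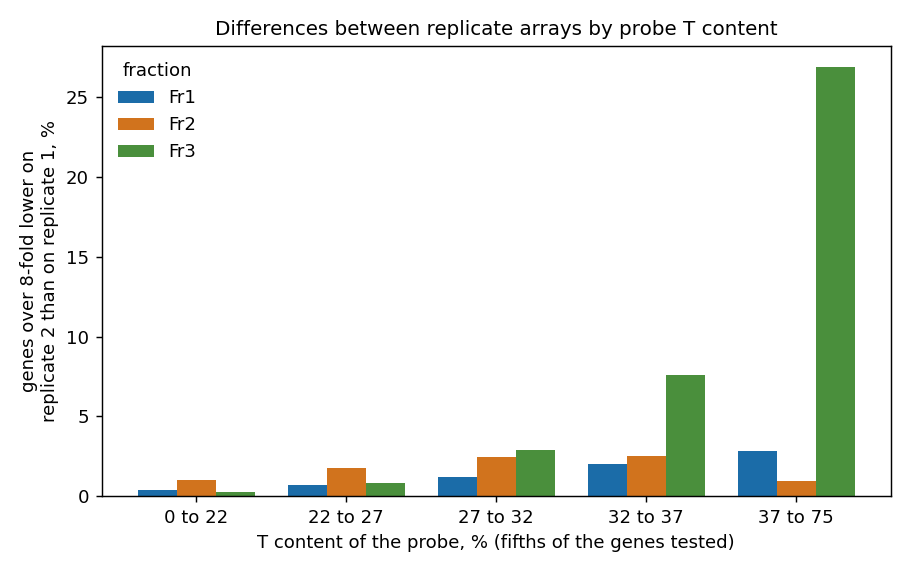
Share of genes over 8-fold lower on replicate 2 than on replicate 1 (vertical axis, %) in 5 bins of probe T content (horizontal axis, %), with 1 bar per fraction. For Fr3 the bar reached 26.8% in the bin with most T and was 0.264% in the bin with least T.

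The sort markers gave the following levels (log2 relative to the array's 75th percentile, mean ± SD, n = 2 arrays per fraction). Mrc1, which encodes the mannose receptor CD206 (chromosome 2, 14253273 to 14253332, mm9), was at 3.23 ± 0.79 in Fr3 and 0.49 ± 0.22 in Fr2, and was not well above background in Fr1 (−3.80 ± 0.42). Its level in Fr3 was at least 44.9-fold that in Fr1 (limma adjusted p = 0.0851), and its level in Fr2 was at least 6.72-fold that in Fr1 (adjusted p = 0.239). Between Fr3 and Fr2 its log2 difference was 2.74 ± 0.62 (SE, adjusted p = 0.259). Itgax, which encodes CD11c (chromosome 7, 135294052 to 135294111), was at 2.53 ± 0.25 in Fr1, 1.99 ± 1.11 in Fr2 and 0.58 ± 0.53 in Fr3. Although Fr2 was sorted as CD11c-negative, the log2 difference between Fr1 and Fr2 was 0.54 ± 0.70 with overlapping arrays (adjusted p = 0.849), and without the second Fr2 array it turned to −0.24. Adgre1, which encodes the antigen F480 (chromosome 17, 57622843 to 57622902), was bright in all fractions, at 4.44 ± 0.07 in Fr1, 5.95 ± 0.02 in Fr2 and 5.39 ± 0.10 in Fr3. No marker passed over all genes in any comparison in the main fit. Without the first Fr3 array the fitted log2 value of Mrc1 (Fr1 minus Fr3) was −6.47, smaller in size than with all arrays. That fit keeps only the Fr3 array that was low at T-rich probes. Another probe of Itgax (Fr1 against Fr2) and of Adgre1 (Fr2 against Fr3) had the opposite sign.

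**Figure D2:**
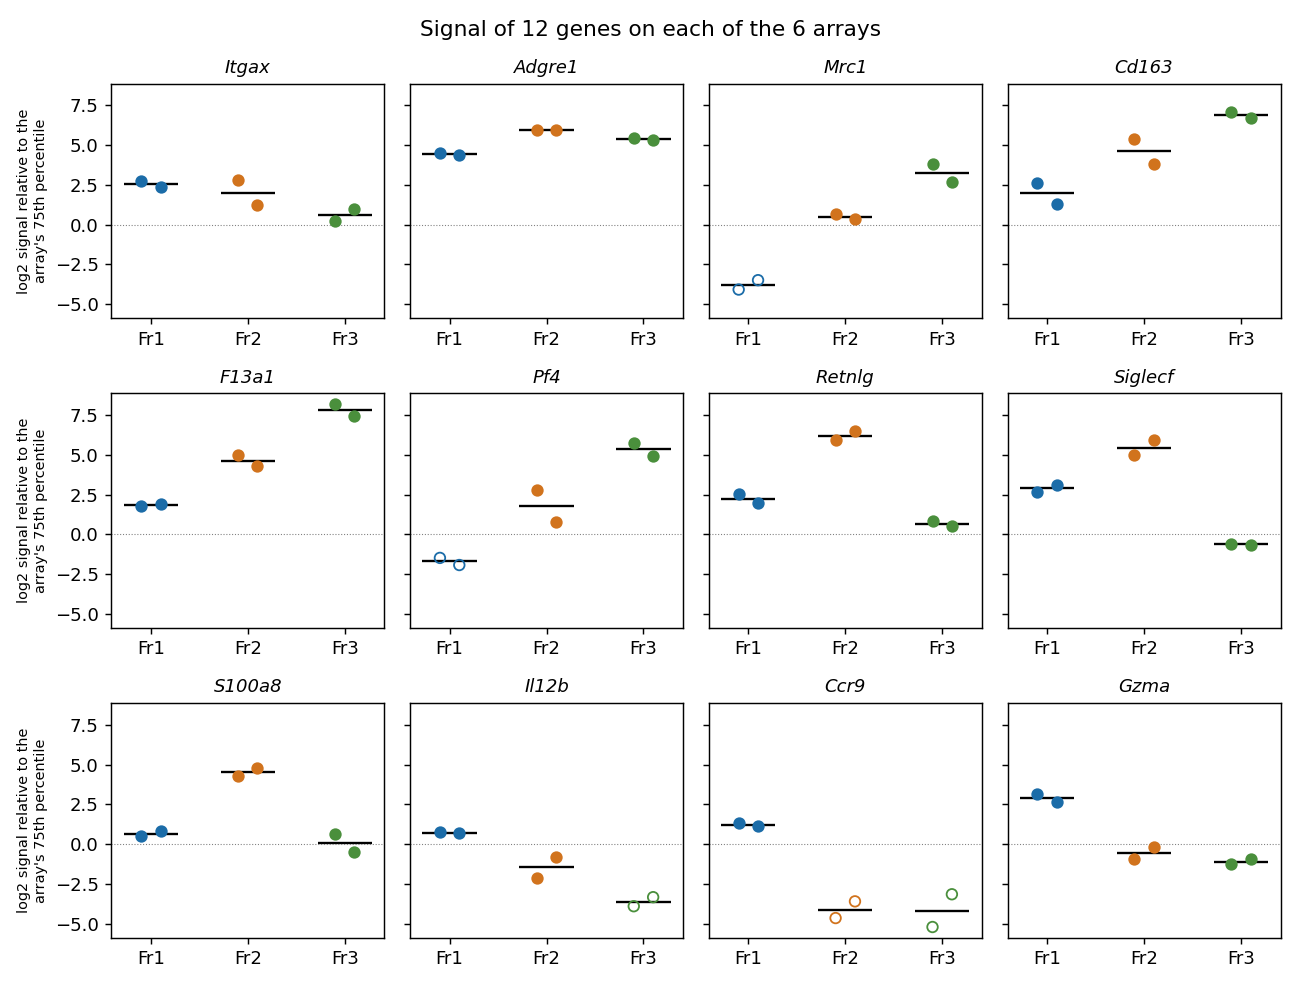
Log2 signal relative to the array's 75th percentile (vertical axis) of 12 genes in Fr1, Fr2 and Fr3; each point is 1 array, the line is the mean of 2 arrays, and open points mark fractions in which the chosen probe was not well above background on both arrays. The CD206 gene Mrc1 averaged 3.23 in Fr3, 0.49 in Fr2 and −3.80 in Fr1.

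In the values that follow, a number with ± is a log2 difference with its SE, from 2 arrays per fraction, given in favour of the fraction named as higher. Adjusted p-values of lists are camera's. Except for Gm2042 below, no gene passed over all genes tested, so members of a list are called higher only where they passed adjusted over the list alone. Some dim genes were well above background on 1 of 2 arrays: Pf4, Rnase2a, Ngp and Fcgrt in Fr1, Il2rb, Fcgrt, Lyve1 and Stab1 in Fr2, and Cd207, Ccr3, Havcr2, Chil3 and Camp in Fr3.

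Fr1 was compared with Fr3 to set the CD11c-positive fraction against the CD206-high macrophages. Fr3 was richer in genes of resident tissue macrophages. F13a1 (5.97 ± 0.58), Pf4 (7.07 ± 0.78) and Cd209f (at least 59.5-fold) were higher in Fr3; they encode a coagulation factor subunit, the chemokine platelet factor 4 and a C-type lectin. The haemoglobin scavenger receptor gene Cd163 (4.91 ± 0.77), the endocytic receptor gene Stab1 (4.22 ± 0.83), the selenium transport gene Selenop (4.02 ± 0.69) and the chemokine gene Ccl24 (4.42 ± 0.68) were higher there too. F13a1 (chromosome 13, 36959214 to 36959273) was at 7.82 ± 0.53 in Fr3 and 1.85 ± 0.07 in Fr1 (mean ± SD, n = 2), and Cd163 (chromosome 6, 124280484 to 124280543) at 6.87 ± 0.26 and 1.96 ± 0.96. Fr1 was richer in Ccr9 (at least 14.1-fold) and Spib (at least 17.6-fold), which encode a chemokine receptor and a transcription factor, and in Il12b, which encodes the shared subunit of the cytokines IL-12 and IL-23. Il12b was at 0.73 ± 0.03 in Fr1 and not well above background in Fr3 (SD, n = 2).

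Of the resident CD206-high macrophage list, 21 of 28 tested members were higher in Fr3 adjusted over the list alone (0 over all genes), the rest did not pass, and the median difference was 3.98 (camera adjusted p = 2.09e-23; adjusted p = 0.269 with an estimated correlation). In the macrophage core list 2 of 22 passed (adjusted p = 1.87e-06; adjusted p = 0.269 with an estimated correlation). These were Selenop and the glutamine synthetase gene Glul (3.25 ± 0.64). In the complement and apoptotic cell uptake list 7 of 24 were higher in Fr3 and 1 in Fr1 (adjusted p = 5.60e-04; adjusted p = 0.393 with an estimated correlation). They included Stab1, the bridging protein genes Gas6 (3.13 ± 0.68) and Pros1 (3.13 ± 0.69) and the properdin gene Cfp (2.26 ± 0.58). Among scavenger, lectin and Fc receptors 8 of 22 were higher in Fr3 (adjusted p = 0.00541; adjusted p = 0.393 with an estimated correlation). The neonatal Fc receptor gene Fcgrt (4.03 ± 0.66) and the lectin gene Clec4a1 (2.65 ± 0.58) were among them, beside Cd163 and Stab1. The alternative activation list had 6 members higher in Fr3 and 1 in Fr1 of 20 (adjusted p = 0.00334; adjusted p = 0.269 with an estimated correlation). The ribonuclease gene Rnase2a (5.14 ± 0.78) was higher in Fr3 beside Mrc1, Ccl24 and Cd163. The cDC2 list was also called toward Fr3 (adjusted p = 0.0173; adjusted p = 0.393 with an estimated correlation), with 0 of 13 members passing. Its lectin genes Clec10a (2.98 ± 0.90) and Mgl2 (2.54 ± 0.81) did not pass within it and are also on the resident macrophage list. Genes of dissociation stress moved with Fr3 as well (adjusted p = 0.00179; adjusted p = 0.404 with an estimated correlation), with 1 of 21 members, the immediate early gene Ier3 (3.47 ± 0.63), passing. Without the first Fr3 array the calls of cDC2, scavenger receptors and dissociation stress ended. Their means over members (Fr1 minus Fr3) were −0.65, −0.67 and −0.54, against −0.83, −1.003 and −0.78 with all arrays. Without the second Fr1 array the call of cDC2 ended too (mean −0.49 against −0.83). With probes over 30% T left out, cDC2 was not called (camera adjusted p = 0.540, mean −0.40 against −0.83 with all probes). Nor was alternative activation (camera adjusted p = 0.126, mean −1.10 against −1.33). Scavenger receptors were not called with only probes above background on all arrays (camera adjusted p = 0.0537, mean −0.82 against −1.003). The same held for cDC2 with the mean of all probes (camera adjusted p = 0.0719, mean −0.70 against −0.83).

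Toward Fr1, 4 dendritic cell lists were called against Fr3 (and none of them against Fr2, as given below). The pan conventional DC list had a median difference of 0.95 (adjusted p = 1.74e-04; adjusted p = 0.269 with an estimated correlation), although 0 of 20 members passed adjusted over the list alone. Its smallest p-values were those of the inhibitory receptor gene Btla (at least 2.69-fold) and the transcription factor gene Bcl11a, whose probe was not well above background in Fr3. In the cDC1 list 2 of 11 were higher in Fr1 (adjusted p = 0.00372; adjusted p = 0.269 with an estimated correlation). These were Itgae (at least 1.55-fold) and Clec9a (at least 3.55-fold), which encode the integrin CD103 and a receptor for dead cells. In the mature migratory DC list Il12b alone passed of 17 (adjusted p = 0.00386; adjusted p = 0.269 with an estimated correlation), and the chemokine receptor gene Ccr7 (1.91 ± 0.56) did not. In the Langerhans cell list the langerin gene Cd207 (3.32 ± 0.77) passed of 7 (adjusted p = 0.0164; adjusted p = 0.269 with an estimated correlation). Lists of other cell types moved with Fr1 too. In plasmacytoid DC, Ccr9 and Spib passed of 14 (adjusted p = 8.58e-04; adjusted p = 0.269 with an estimated correlation). In T and NK cell, 3 of 16 were higher in Fr1 and 1 in Fr3 (adjusted p = 0.0164; adjusted p = 0.393 with an estimated correlation). The 3 were the granzyme genes Gzma (3.99 ± 0.57) and Gzmb (at least 3.07-fold) and the IL-2 receptor gene Il2rb (3.14 ± 0.73). The eosinophil list had 3 of 12 higher in Fr1 (adjusted p = 0.0173; adjusted p = 0.393 with an estimated correlation), namely Prg2 (at least 14.0-fold), Siglecf (3.51 ± 0.59) and Ccr3 (4.43 ± 0.88). The neutrophil list had 0 of 18 (adjusted p = 0.0107; adjusted p = 0.393 with an estimated correlation). Without the first Fr3 array only pan conventional DC of these 8 lists was still called. The means over members (Fr1 minus Fr3) of the other lists stayed positive. They were 1.34 for cDC1, 1.02 for mature migratory DC, 1.28 for Langerhans cell and 1.299 for plasmacytoid DC. With all arrays they were 1.22, 1.13, 1.17 and 1.57. The means of T and NK cell (0.52 against 0.93), eosinophil (0.71 against 1.11) and neutrophil (0.74 against 0.65) stayed positive too. With all arrays the medians were 0.73 for cDC1 and 1.48 for mature migratory DC. With dim members at their bounds these medians were 0.64 and 1.24. With only probes above background on all arrays, cDC1 and mature migratory DC were not called (camera adjusted p = 0.0912 and 0.270). Their means were 0.52 and 0.26, against 1.22 and 1.13 with the filter used elsewhere. Plasmacytoid DC (camera adjusted p = 0.187, mean 0.41 against 1.57) and eosinophil (0.444, mean 0.27 against 1.11) were not called there either. Nor were mature migratory DC (camera adjusted p = 0.0603, mean 0.08 against 1.13) and eosinophil (0.0522, mean 0.34 against 1.11) with normexp. The T and NK cell list was not called with no filter (camera adjusted p = 0.0866, mean 0.71 against 0.93). The neutrophil call also ended without the second Fr3 array (mean 0.55 against 0.65). The calls of neutrophil (mean 0.48 against 0.65) and T and NK cell (0.82 against 0.93) ended without the second Fr1 array. The call of eosinophil ended without the first Fr1 array (mean 1.16 against 1.11).

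Over all genes, limma called 1 gene between Fr1 and Fr3, Gm2042, a gene model known only by number (chromosome 12, 89199059 to 89199118), named after its values were seen. It was at 3.19 ± 0.10 (SD, n = 2) in Fr3 and not well above background in Fr1 or Fr2, which made it at least 43.6-fold higher in Fr3 than in Fr1 (adjusted p = 0.0448). At an unadjusted p under 0.05 there were 1690 genes, 579 higher in Fr1 and 1111 higher in Fr3, where chance gives 1041. The arrays of the 2 fractions did not overlap for 35.7% of genes (33.3% by chance). The count was 1476 genes without the first Fr3 array, 1286 of them higher in Fr1, and 0 without any other single array or with the replicate block. Both fractions lay on the same slide, and the fit on these 4 arrays alone called 0 genes and 16 lists, against 15 lists over all 6 arrays. Without the first Fr3 array 5 lists were called.

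Fr1 was compared with Fr2 to set CD11c-positive cells against CD11c-negative F480-positive cells, both CD206-negative. Fr2 was richer in granulocyte genes. The granule protein genes Camp (5.51 ± 0.57), Ltf (at least 9.73-fold) and Ngp (4.99 ± 0.77) and the resistin-like gene Retnlg (3.97 ± 0.57) were higher in Fr2, as were the eosinophil receptor gene Siglecf (2.56 ± 0.59) and the ribonuclease genes Ear1 (3.12 ± 0.79), Ear2 (3.40 ± 0.81) and Ear6 (3.39 ± 0.86). The chitinase-like gene Chil3 (at least 54.5-fold) was higher in Fr2 too. Camp (chromosome 9, 109749911 to 109749970) was at 3.62 ± 0.08 in Fr2 and −1.89 ± 0.44 in Fr1 (mean ± SD, n = 2). Fr1 was richer in Ccr9 (at least 18.0-fold) and Spib (at least 22.5-fold) and in the lymphocyte genes Il2rb (4.64 ± 0.73), Gzma (3.45 ± 0.57), Gzmb (at least 3.93-fold) and Icos (2.40 ± 0.70).

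By list, 8 of 18 neutrophil genes were higher in Fr2 adjusted over the list alone and 0 over all genes, with a median difference of 1.68 (adjusted p = 9.75e-11; adjusted p = 0.331 with an estimated correlation). The eosinophil list had 5 of 12 higher and a median of 1.86 (1.25 with dim members at their bounds; adjusted p = 4.67e-05; adjusted p = 0.351 with an estimated correlation). The monocyte list had 3 of 23 (adjusted p = 3.62e-06; adjusted p = 0.320 with an estimated correlation): Chil3, the interferon-induced gene Ifitm6 (at least 8.01-fold) and the haptoglobin gene Hp (3.05 ± 0.68). Alternative activation had 7 of 20 higher in Fr2 and 1 in Fr1 (adjusted p = 0.00377; adjusted p = 0.351 with an estimated correlation), with Chil3, Mrc1, Rnase2a (5.05 ± 0.78) and Cd200r1 (at least 1.31-fold). The resident CD206-high macrophage list had 4 of 28 higher in Fr2 (adjusted p = 0.00483; adjusted p = 0.452 with an estimated correlation), namely Mrc1, F13a1 (2.79 ± 0.58), Pf4 (3.49 ± 0.78) and Ccl24 (3.00 ± 0.68). Another probe of F13a1 had the opposite sign. In the macrophage core list the kinase gene Camk1 (at least 6.24-fold) passed of 22 (adjusted p = 4.52e-04; adjusted p = 0.351 with an estimated correlation). In cDC2 the IL-33 receptor gene Il1rl1 (3.30 ± 0.68) passed of 13 (adjusted p = 0.00483; adjusted p = 0.351 with an estimated correlation). Among scavenger, lectin and Fc receptors 0 of 22 passed (adjusted p = 0.00548; adjusted p = 0.357 with an estimated correlation). Matrix remodelling and angiogenic factors had 2 of 24 (adjusted p = 0.00548; adjusted p = 0.351 with an estimated correlation). They were Timp3 (3.79 ± 0.66) and Ctsk (at least 1.31-fold), which encode a metalloproteinase inhibitor and cathepsin K. Dissociation stress also had 2 of 21 (adjusted p = 6.54e-04; adjusted p = 0.435 with an estimated correlation), Btg2 (2.71 ± 0.53) and Klf2 (2.68 ± 0.58). Without the first Fr2 array 7 of these calls ended. Their means over members (Fr1 minus Fr2) kept their sign. They were −0.77 for macrophage core, −0.63 for matrix remodelling, −0.95 for alternative activation and −0.76 for cDC2. With all arrays they were −1.10, −0.80, −1.21 and −1.05. The means of dissociation stress (−0.47 against −0.88), scavenger receptors (−0.35 against −0.68) and resident macrophage (−0.41 against −0.92) kept their sign too. With all arrays the medians were −0.49 for resident macrophage, −0.64 for alternative activation and −0.62 for matrix remodelling. With dim members at their bounds these medians were −0.32, −0.54 and −0.50. With normexp the resident macrophage list was not called either (camera adjusted p = 0.156, mean −0.43 against −0.92). The cDC2 list was also not called without the second Fr1 array (mean −0.72 against −1.05). With probes over 30% T left out, cDC2 (camera adjusted p = 0.176) and scavenger receptors (0.0860) were not called. Nor were alternative activation (camera adjusted p = 0.0860) and dissociation stress (0.178). In that order the means were −0.60, −0.58, −0.79 and −0.40, against −1.05, −0.68, −1.21 and −0.88 with all probes.

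Toward Fr1, the plasmacytoid DC list was called with all 14 members on the Fr1 side, 2 of them (Ccr9 and Spib) passing, and a median of 1.28 (adjusted p = 6.02e-06; adjusted p = 0.338 with an estimated correlation). The T and NK cell list had 4 of 16 higher in Fr1, Il2rb, Gzma, Gzmb and Icos (camera adjusted p = 8.84e-04, and 0.357 with an estimated correlation). It was not called with probes over 30% T left out (camera adjusted p = 0.0865, mean 0.84 against 1.26 with all probes). The CD103 gene Itgae (at least 1.99-fold) was higher in Fr1, 1 of 11 cDC1 genes, and that list was not called (adjusted p = 0.210). Nor were pan conventional DC (camera adjusted p = 0.118), mature migratory DC (0.0780) and Langerhans cell (0.566). Some genes of structural tissue were higher in Fr2 in lists that were not called and whose members lay on both sides. In the epithelium list the keratin genes Krt6a (at least 2.24-fold) and Krt14 (at least 1.51-fold), and Perp (at least 3.33-fold) and Sfn (2.11 ± 0.60), passed, while 8 of 15 members lay on the Fr1 side (adjusted p = 0.253). In the fibroblast list the matrix genes Dcn (at least 2.18-fold) and Col3a1 (at least 1.68-fold) passed, while 6 of 13 lay on the Fr1 side (adjusted p = 0.513).

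Over all genes, limma called 0 genes between Fr1 and Fr2 (smallest adjusted p = 0.193). There were 2038 genes at an unadjusted p under 0.05, 694 higher in Fr1 and 1344 higher in Fr2, where chance gives 1041. The arrays did not overlap for 44.8% of genes (33.3% by chance). The fit on only the Fr1 and Fr2 arrays called 13 genes, 12 of them higher in Fr2. Leaving out either Fr3 array gave the same fit for this comparison, because a lone array adds nothing to the spread. In these fits the spread between the Fr3 arrays does not enter, as it does in the main fit. A trended and robust variance gave 1. Camera called 5 lists without the first Fr2 array, against 12 with it. The 2 fractions lay on different slides.

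Fr2 was compared with Fr3 to set the F480-positive fractions with and without CD206 against each other. Fr2 was richer in granulocyte and monocyte genes. These were Prg2 (at least 101-fold), Siglecf (6.07 ± 0.59) and Ccr3 (5.23 ± 0.88) among eosinophil genes, Retnlg (5.54 ± 0.57), Camp (5.56 ± 0.57), S100a8 (4.47 ± 0.63) and Ngp (5.24 ± 0.77) among neutrophil genes, and Chil3 (7.17 ± 0.83), Hp (4.86 ± 0.68) and Ly6c2 (4.33 ± 0.78) among monocyte genes. Siglecf (chromosome 7, 50614417 to 50614476) was at 5.45 ± 0.67 in Fr2 and −0.63 ± 0.05 in Fr3 (mean ± SD, n = 2). S100a8 (chromosome 3, 90473778 to 90473837), which encodes a calcium-binding protein abundant in neutrophils, was at 4.54 ± 0.39 and 0.07 ± 0.82 (mean ± SD, n = 2). Fr3 was richer in the lectin gene Cd209f (5.75 ± 0.72), the folate receptor gene Folr2 (5.13 ± 0.66), the hyaluronan receptor gene Lyve1 (5.30 ± 0.89), Stab1 (4.78 ± 0.83) and Fcgrt (3.95 ± 0.66).

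Adjusted over the list alone, 17 of 28 resident CD206-high macrophage genes were higher in Fr3 and 0 over all genes, with all 28 on the Fr3 side and a median of 2.52 (adjusted p = 4.79e-18; adjusted p = 0.267 with an estimated correlation). In the complement and apoptotic cell uptake list 2 of 24 were higher in Fr3 (adjusted p = 0.00669; adjusted p = 0.603 with an estimated correlation), Stab1 and the bridging protein gene Gas6 (3.12 ± 0.68). That call ended without the second Fr2 array and without the first Fr3 array (mean over members −0.46 and −0.85, Fr2 minus Fr3). It also ended with probes over 30% T left out (camera adjusted p = 0.266, mean −0.80). The same held with only probes above background on all arrays (camera adjusted p = 0.0697, mean −0.64). With all arrays the list's mean was −0.93 and its median −1.10. Toward Fr2, 13 of 18 neutrophil genes were higher, with a median of 3.18 (3.12 with dim members at their bounds; adjusted p = 2.48e-16; adjusted p = 0.191 with an estimated correlation). The eosinophil list had 4 of 12 higher and a median of 2.21 (2.15 with dim members at their bounds; adjusted p = 6.71e-09; adjusted p = 0.267 with an estimated correlation). The monocyte list had 5 of 23 and a median of 1.01 (adjusted p = 5.40e-06; adjusted p = 0.191 with an estimated correlation). The resident macrophage, neutrophil, eosinophil and monocyte lists were called under every alternative that kept camera at the preset correlation. Some members passed in lists that were not called. Those passing toward Fr2 and toward Fr3 numbered 3 and 2 in alternative activation and 3 and 1 among matrix and angiogenic factors. They numbered 1 and 3 in skeletal muscle, 1 and 2 among scavenger, lectin and Fc receptors, and 1 and 0 in each of Langerhans cell and macrophage core. The transglutaminase gene Tgm2 (4.64 ± 0.69) of alternative activation and the vascular growth factor gene Vegfa (2.90 ± 0.58) of matrix factors were higher in Fr2. So were the checkpoint receptor gene Havcr2 (4.97 ± 0.67) among costimulatory and coinhibitory ligands and Krt6a (at least 2.81-fold) in epithelium. The chemokine gene Ccl7 (4.26 ± 0.76), the growth factor gene Hbegf (2.20 ± 0.52) and Ier3 (3.07 ± 0.63) were higher in Fr3.

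Over all genes, limma again called Gm2042 alone between Fr2 and Fr3, at least 70.1-fold higher in Fr3 (adjusted p = 0.0263). At an unadjusted p under 0.05 there were 1856 genes, 1006 higher in Fr2 and 850 higher in Fr3, where chance gives 1041. The arrays did not overlap for 42.1% of genes (33.3% by chance). The count was 988 without the first Fr3 array, 918 of them higher in Fr2, and 0 without any other single array. Without the first Fr2 array 8 lists were called in place of 5. The replicate block and the fit on only these 4 arrays also called 0 genes. The fractions lay on different slides.

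**Figure D3:**
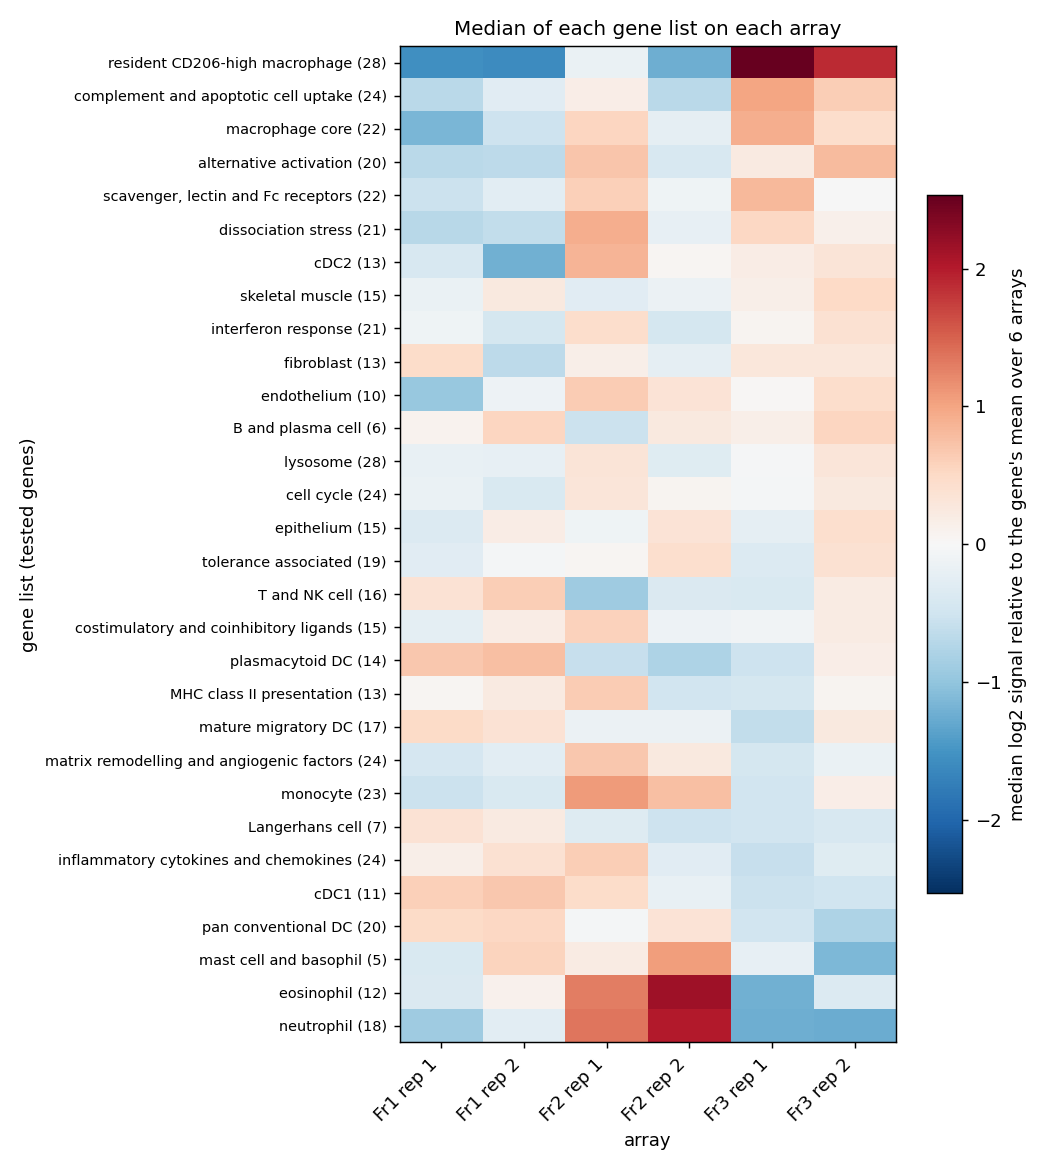
Median log2 signal of each of 30 gene lists on each of the 6 arrays, relative to each gene's mean over the arrays (colour), with the number of tested genes in brackets; lists are ordered by Fr3 against the other fractions. The resident CD206-high macrophage list, at the top, had medians of −0.49 (−0.32 with dim members at their bounds) for Fr1 minus Fr2, −3.98 for Fr1 minus Fr3 and −2.52 for Fr2 minus Fr3.

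The other lists were called in no comparison. The lowest adjusted p over the 3 comparisons was 0.0539 for mast cell and basophil genes, 0.0789 for inflammatory cytokines and chemokines, 0.0811 for cell cycle, 0.118 for endothelium, 0.121 for skeletal muscle and 0.149 for lysosome. It was 0.253 for epithelium, 0.266 for each of tolerance associated, interferon response and B and plasma cell genes, 0.303 for costimulatory and coinhibitory ligands, 0.464 for MHC class II presentation and 0.513 for fibroblast genes. The lysosomal proton pump gene Atp6v0d2 was not well above background in Fr1 and was at least 15.5-fold higher in Fr2 and at least 6.81-fold higher in Fr3, passing adjusted over the list alone in both. Ccl7, a monocyte-attracting chemokine gene, was at least 35.8-fold higher in Fr3 than in Fr1. Of MHC class II genes, H2-DMb2 leaned toward Fr3 by 1.60 ± 0.75 and H2-Aa toward Fr1 by 0.92 ± 0.68 between Fr1 and Fr3, and neither passed. The median, mean and test of a list differed in sign for 2 lists in Fr1 against Fr2 (Langerhans cell, epithelium). They did for 3 in Fr1 against Fr3 (monocyte, matrix remodelling, fibroblast) and for 5 in Fr2 against Fr3 (cDC2, interferon response, cell cycle, B and plasma cell, epithelium), and none of these was called (0 in each comparison).

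Camera called 12 lists for Fr1 against Fr2, 15 for Fr1 against Fr3 and 5 for Fr2 against Fr3. With an estimated correlation 0 lists were called in each comparison, and fry called 2, 4 and 3. The estimate lay below the preset 0.01 for monocyte (−0.0137), pan conventional DC (−0.0295), mature migratory DC (−0.0153) and Langerhans cell (−0.153). Still, the unadjusted camera p of monocyte between Fr1 and Fr2 rose from 2.41e-07 to 0.0107. For these lists a higher correlation therefore does not account for the lost calls, and the reason was not tested. The moderated F-test over the 3 fractions called 1 gene, Gm2042 (adjusted p = 0.0436), with 2084 at an unadjusted p under 0.05. Gm2042 was also the 1 gene called higher in one fraction, Fr3, than in both others, against 0 for Fr1 and 0 for Fr2. In 50 simulations with no effect the count for Fr3 averaged 0.02 and reached 1, and independent lists would share 4.80e-05 genes. Both counts were 0 without any single array other than the first Fr3 array, without which they were 1153 and 39.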

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

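The base-content and all-array percentile alternatives were chosen after the data had been seen. No called result reversed under any of the 24 alternatives. Under the deposited table, the mean of all probes, the 2-fold minimum and the T content curve every count of genes and of lists stayed within 1.5 times its value. The counts of genes called, 0 for Fr1 against Fr2 and 1 each for Fr1 against Fr3, Fr2 against Fr3, the F-test and genes higher in one fraction than in both others, moved otherwise as follows; the cause was not tested unless given. With normexp they were 0 for Fr1 against Fr3, 8 for Fr2 against Fr3, 0 for the F-test and 0 fraction-specific; with quantile scaling the F-test called 0. Scaling to the median of probes above background on all arrays, array weights, no filter, and scaling to the 75th percentile of probes above background on all arrays each gave 0 for Fr1 against Fr3, 0 for the F-test and 0 fraction-specific. No filter, which tests more genes, also called 8 lists for Fr2 against Fr3. With only probes above background on all arrays, Fr2 against Fr3 gave 9 genes, the F-test 3 and fraction-specific genes 0. A trended and robust variance gave 1, 8 and 11 genes in the 3 comparisons and 22 in the F-test, and Mrc1 passed between Fr1 and Fr3 (adjusted p = 0.0346, in a range of 0.0142 to 0.610 over alternatives). The fitted log2 value there was −7.02 and, as Mrc1 was not well above background in Fr1, rests on signal below that floor, as do all fitted Mrc1 values against Fr1. Over alternatives they ranged from −7.58 to −2.63 for Fr1 against Fr3 and from −4.58 to −0.73 for Fr1 against Fr2, the smallest with normexp, whose offset draws dim signals together by construction. With only the arrays compared the counts were 13, 0 and 0; at adjusted p under 0.01, which is stricter, they were 0, 0 and 0, with 0 for the F-test and 0 fraction-specific. Leaving out probes over 30% T gave 3, 12 and 56 genes, 43 in the F-test and 5 fraction-specific. Leaving out each array in turn gave 0 to 13 genes for Fr1 against Fr2, 0 to 1476 for Fr1 against Fr3, 0 to 988 for Fr2 against Fr3, 0 to 1153 in the F-test and 0 to 39 fraction-specific, the highest without the first Fr3 array (for Fr1 against Fr2, without either Fr3 array). The fitted Mrc1 value between Fr1 and Fr3 ranged from −7.58 to −6.47 with an array left out. The −6.47 came without the first Fr3 array, which leaves only the Fr3 array that was low at T-rich probes. A lone array is assumed to vary like the other fractions. Lists called ranged from 5 to 16 for Fr1 against Fr2 (lowest without the first Fr2 array), 5 to 16 for Fr1 against Fr3 (lowest without the first Fr3 array) and 4 to 8 for Fr2 against Fr3. An estimated correlation gave 0, 0 and 0 lists and fry 2, 4 and 3. Of the 32 list calls, 11 ended without the first Fr3 array, 8 with probes over 30% T left out, 7 without the first Fr2 array, 6 with probes above background on all arrays, 4 without the second Fr1 array and 3 with normexp, and at most 1 under any other setting with the preset correlation. Among named genes 42 of 6599 signs turned, 6 of them among 4285 values with an unadjusted p under 0.05, and among sort markers 4 of 174. The median of all genes moved by over 0.1 (log2) with the median of probes above background (0.11 for Fr1 against Fr3), the all-array 75th percentile (0.19 for Fr1 against Fr2 and 0.17 for Fr1 against Fr3), no filter (0.27, 0.17 and −0.20) and probes over 30% T left out (−0.12 for Fr1 against Fr3 and −0.20 for Fr2 against Fr3), and, with an array left out, by −0.23 to 0.16 for Fr1 against Fr3 and −0.16 for Fr2 against Fr3. Slide as a block was not run. Between 44.6% and 52.4% of spots were well above background, so genes dim in a fraction have only bounds there.

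The replicate numbers share no stated animal or day. Deviations from the fraction means correlated at 0.118 between Fr1 and Fr2, 0.433 between Fr1 and Fr3 and 0.0458 between Fr2 and Fr3. The highest was that of the fractions that shared a slide. Their replicate differences also went most with probe T content (Spearman rho −0.371 in Fr1 and −0.411 in Fr3, against −0.112 in Fr2). Whether the numbers pair samples therefore stays open. With the replicate block 0 genes were called for Fr1 against Fr3, 0 for Fr2 against Fr3, 0 by the F-test and 0 as fraction-specific, and 0 of the 32 list calls were lost.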

Other observations

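The genes in this and the next paragraph, and the explanations tested below, were chosen only after results had been seen. The list tests and most alternatives cited with them had been fixed before. The predictions on another cell type in the first Fr3 sort and on the dendritic cell lists were written before the values that test them were computed. A set of 7043 genes lay outside the lists, did not match the name filter and had probes of at most 30% T. Of them, 10.5% were higher on both Fr3 arrays than on all others (6.67% by chance). None was called by limma in the main fit, with no alternative applied. Genes were ranked by the smaller of the log2 differences to the other fractions' means, with each array of those fractions set no lower than its lowest signal well above background, so the values in brackets are lower bounds where signals were dim. The top genes of Fr3 included Hal (4.94), which encodes a histidine-degrading enzyme, Ednrb (3.96), an endothelin receptor gene, Asgr2 (3.41), a lectin receptor gene, and Fcna (3.01), which encodes the complement lectin ficolin A. Hal was at 3.54 ± 0.81 and Ednrb at 2.53 ± 0.62 in Fr3 (SD, n = 2, F-test adjusted p = 0.114 and 0.275 in the main fit). With probes over 30% T left out, limma called Hal between Fr1 and Fr3 and between Fr2 and Fr3. A trended and robust variance also called it between Fr1 and Fr3.

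In Fr2 the share was 10.7%, and the leading genes included the antimicrobial peptidoglycan receptor gene Pglyrp1 (3.68), the eosinophil-type ribonuclease gene Ear7 (2.77), the basement membrane collagen gene Col4a1 (2.72), the trefoil peptide gene Tff2 (4.02), the lipase gene Lipf (4.14) and the calmodulin-like gene Calml3 (3.35). Lipf was at 6.79 ± 0.80 in Fr2 (SD, n = 2). The mucin gene Muc5b (2.73) was at 5.91 ± 1.07 in Fr2 (SD, n = 2). It was at 3.33 and 3.04 on the Fr3 arrays and at −2.91 and −1.79 on the Fr1 arrays. A trended and robust variance called Muc5b between Fr1 and Fr2, as did the fit with probes over 30% T left out. No gene of the set was called in the main fit (F-test adjusted p = 0.114 for Tff2 and 0.337 for Lipf). With probes over 30% T left out, limma called Tff2 and Pglyrp1 between Fr2 and Fr3, but not between Fr1 and Fr2. The fit on only the arrays compared called Calml3 between Fr1 and Fr2. In Fr1 the share was 4.19%, below the 6.67% of chance, with the lymphocyte receptor gene Gpr171 (3.24) and the type I interferon genes Ifnb1 (2.18) and Ifnab (2.25) among the top (F-test adjusted p = 0.167, 0.162 and 0.327).

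On the second Fr3 array 1602 genes were over 8-fold lower than on the first. The share of such genes was 0.264% in the fifth of genes with least T in the probe and 26.8% in the fifth with most, a ratio of 102, so a loss tied to T content is a candidate explanation. The A content of the probe did not go with the difference (Spearman rho 0.0572 across genes, against −0.411 for T). That alone would count against AT content with A and T alike. GC content, however, went with the difference about as strongly as T (rho 0.427), so these correlations do not separate T from AT content. Cells of another type in the first Fr3 sort are argued against by the lists of other cell types, whose lowest median between the arrays was −0.20. The difference also went with T content within Fr1 (rho −0.371) and less within Fr2 (−0.112), and among olfactory and vomeronasal receptor genes 110 of 396 (27.8%) were affected against 7.31% of other genes. Both arrays are of 1 fraction, no biological explanation other than cell composition was tested, and which step made the difference stays open.

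Granulocyte genes were higher in Fr2: 20 of 30 tested neutrophil and eosinophil genes (66.7%) were higher on both Fr2 arrays than on all others, against 10.3% of all genes and 6.67% by chance. With an estimated correlation neither list was called, at adjusted p = 0.331 (neutrophil) and 0.351 (eosinophil) against Fr1 and 0.191 and 0.267 against Fr3. A slide or scan effect acting through signal level and T content is argued against by random lists matched on both. The median of these genes (2.51 over the mean of the other fractions) lay above all 10000 of them, at percentile 100, with the highest random median at 0.69. All 30 genes were well above background on both Fr2 arrays, and the random lists were not matched on this. That favours a high median, and a high share, in Fr2. A difference in sorting or RNA preparation between slides cannot be told apart from the fraction, because 0 slides held Fr2 and another fraction. Granulocytes within the Fr2 gate may be the source, as eosinophils carry F480 and the stated gate holds no granulocyte marker, but neutrophils largely lack F480 and an F480-positive gate would remove most of them; levels in Fr2 were, for example, S100a8 at 4.54 ± 0.39 and Retnlg at 6.22 ± 0.44 (SD, n = 2), and 2 of the 30 are on another list as well.

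The pan conventional DC, cDC1, mature migratory DC and Langerhans cell lists were called higher in Fr1 than in Fr3, as were plasmacytoid DC (adjusted p = 0.269 with an estimated correlation) and T and NK cell (adjusted p = 0.393 with an estimated correlation), while cDC2 was called the other way (adjusted p = 0.0173; adjusted p = 0.393 with an estimated correlation; kept under 16 of 20 alternatives with the preset correlation). With the T content curve taken off each array 4 of the 4 lists were still called, and without the second Fr3 array 4 of 4 were too, which argues against the T content of the probes and against the second Fr3 array alone as the whole cause. Without the first Fr3 array 1 of the 4 was called, and with an estimated correlation 0 lists were. Without that array the means over members were 1.34, 1.28 and 1.02 for cDC1, Langerhans cell and mature migratory DC. With all arrays they were 1.22, 1.17 and 1.13. With only probes above background on all arrays cDC1 (camera adjusted p = 0.0912, mean 0.52) and mature migratory DC (0.270, mean 0.26) were not called. Nor was mature migratory DC with normexp (camera adjusted p = 0.0603, mean 0.08). Between Fr1 and Fr2 none of the 4 lists was called. Their camera adjusted p there was 0.118 (pan conventional DC), 0.210 (cDC1), 0.0780 (mature migratory DC) and 0.566 (Langerhans cell). Between Fr2 and Fr3 none was called either, but pan conventional DC had a median of 1.04 toward Fr2 (camera adjusted p = 0.0539). The lists thus set Fr1 apart from Fr3 but not from Fr2. A difference in cell type between the sorted fractions could account for these values and stays a hypothesis, resting on 2 arrays per fraction.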
